A study of Danio rerio with 8 samples.

How the data were processed

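Bulk RNA was sequenced from 8 samples of zebrafish (Danio rerio) larvae at 5 days postfertilization, 4 kept in DMSO and 4 exposed to TCDD from 2 hours postfertilization. The labels give the tissue as heart, total RNA extracted with Trizol and libraries made with a SMARTER mRNA-Seq kit. The TCDD concentration, the number of larvae per sample and whether the samples came from separate clutches are not given in the sources used here, so p values measure the spread between these samples. The replicate numbers 1 to 4 were not taken to pair the samples, so a fit with the number as a block was made only as an alternative.

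The deposited files hold, per library, an estimated count, a TPM and an FPKM for each of 25725 genes with NCBI gene identifiers and symbols. The estimated counts are expected counts, deposited without normalization: 11.43 to 11.98% of genes have a fraction. The TPM and FPKM columns, both scaled for transcript length and library size, were computed by the authors. The submitters' processing notes name Bowtie2 and the GRCz11 assembly, while the quantifier and the annotation are not given in the sources used here. A gene table of another assembly served for symbols and synonyms only, so no coordinates are given. The files show 17 symbols turned into dates and 21 symbols shared by 42 rows, and genes were kept apart by identifier.

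The total estimated counts of the DMSO libraries 1 to 4 were 15183023, 14048563, 14744910 and 14650013, and those of the TCDD libraries 14331225, 14080977, 14478768 and 14219773. Genes above 0 numbered 24129 to 24444 per library, and the 10 most abundant genes held 8.15 to 10.35% of the counts. The floor of 3 counts was 0.198 to 0.214 CPM. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries was a copy: the lowest chi-square per degree of freedom between libraries of a group was 7.78.

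Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group, TMM factors, quasi-likelihood F-test with robust estimation, treatment as the term, two-sided). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called changed. The biological coefficient of variation was 18.3%. The SE of a log2 fold change was taken as its size over the square root of F. CPM of single genes used TMM-scaled library sizes. The summed CPM of lists and the ranges of apoa1b, fabp10a and myl7 over the 8 libraries used library size alone, as shares of a library. The 38 gene lists and the rules below were fixed before the data were examined. Of 836 memberships 808 were matched by symbol and 7 by synonym, and 21 were not matched, among them the 13 mitochondrially encoded genes, so that list was not tested. The gene vmhc is listed as myh7, and wfikkn1 and slc7a11 were below the filter. Each of the other 37 lists was tested with camera at a preset correlation of 0.01 (limma 3.58.1), and beside it with an estimated correlation and with fry, with adjustment over the lists. The count adjusted over the list alone used the members' p values only. A list that moves both ways can have a median and a camera direction of different sign, as with the skin list (median -0.15, camera direction up).

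The named genes were set by 3 rules. The first took the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM, no overlap between the groups and a symbol that is not a clone name (772 genes qualified). The second took, whatever their values, cyp1a, cyp1b1, cyp1c1, cyp1c2, ahrra, ahrrb, tiparp, ahr2, nqo1, gpx4a, gpx4b, acsl4a, slc7a11, ptgs2a, hmox1a, sox9b, nppa, nppb, myl7, vmhc and myh6. The third took up to 4 members with the smallest p in each list, of which the text gives those with the smallest. A gene outside these rules is named as chosen after its values were seen.

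Summed CPM of cell type lists and the share of counts from short genes were compared by exact two-sided permutation tests, for which 4 against 4 gives at least p = 0.0286. Transcript lengths were implied by the ratio of count to FPKM. They ran down to 36.8 bases and were not checked against an annotation, so they may differ from full transcript lengths. The calculations also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

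Alternatives were DESeq2 1.42.0, limma-voom, edgeR without robust estimation, RLE and upper quartile factors, library size alone, no filter, filters of 1 CPM in 4 samples and of a mean of 10 CPM, the replicate block, the 10 most abundant genes or the genes of other tissues left out, other adjusted p thresholds, and each library left out in turn. Offsets from a smooth of log2 CPM on implied length (span 0.3) and leaving out both DMSO 1 and TCDD 2, and TMM-scaled library sizes for the summed CPM of lists, were chosen after the data were seen. The correction for length and GC content set beforehand was replaced by length alone, since GC content was not used here, and the pseudocount and quantile alternatives did not apply to counts.

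The test was run on simulated data with this design, 10 simulations with the mean and dispersion of each gene taken from these libraries. The dispersions were those that edgeR estimated, which may favour edgeR over the other tools. A further set of genes was raised slightly, and its calls count among all calls but never as false. Each simulation changed far fewer genes than were called in the data. Genes were drawn independently, without a trend with length or differences shared by the genes of a library. The shares called and the shares of false calls hold for that setting only. edgeR called 9 of 489 genes with a 1.25-fold change, 82 of 494 with 1.5-fold, 328 of 491 with 2-fold and 476 of 489 with 4-fold, and 76 of 983 calls were false (7.73%). DESeq2 made 261 false calls of 1297 (20.1%) and limma-voom 58 of 893 (6.49%).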

Results

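RNA was sequenced from 8 samples of zebrafish larvae at 5 days postfertilization whose tissue is given as heart. The comparison had 4 samples of larvae kept in the solvent DMSO and 4 of larvae exposed to TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin, a ligand of the aryl hydrocarbon receptor, AHR) from 2 hours postfertilization. Each library listed 25725 genes. The total estimated count per library ran from 14048563 (DMSO 2) to 15183023 (DMSO 1), and 3 counts, the smallest level taken as detected, were 0.198 to 0.214 CPM (the count scaled to the library size). In a principal component analysis the first component held 33.4% of the variance and put all 4 DMSO libraries (-36.0 to -18.75) apart from the 4 TCDD libraries (6.89 to 46.7). The second component held 28.5% and set DMSO 1 (59.9) and TCDD 2 (28.95) apart from the other 6. CPM values below are means ± SD over n = 4 samples of a group, on TMM-scaled library sizes for single genes and on library size alone for the sums of lists, log2 fold changes are TCDD against DMSO ± SE, and adjusted p values come from edgeR unless a list test is named.

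The comparison of TCDD with DMSO asked which transcripts differ in the hearts of larvae exposed to TCDD, with AHR target genes and lipid peroxidation named in the study's title. The gene with the strongest evidence was cyp1a (NCBI gene 140634), the cytochrome P450 most used as a marker of AHR activation in fish. It rose 65.6-fold, from 118 ± 30.7 to 7774 ± 1477 CPM (log2 fold change 6.04 ± 0.26, adjusted p = 6.0e-07). The 4 DMSO libraries held 164, 101, 106 and 102.5 CPM of cyp1a, and the 4 TCDD libraries held 7469, 9744, 7709 and 6173 CPM.

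Every tested member of the AHR target list rose, 10 of 10 over all genes and 10 adjusted over the list alone, with a median log2 fold change of 5.15. The other family 1 cytochromes were cyp1b1 (3.01 ± 0.688 to 125 ± 39.9 CPM; 5.37 ± 0.28, adjusted p = 2.4e-06), cyp1c1 (31.1 ± 6.24 to 991 ± 228 CPM; adjusted p = 6.0e-07) and cyp1c2 (5.77 ± 1.55 to 229 ± 75.6 CPM; adjusted p = 2.7e-06). The AHR repressor gene ahrra rose from 0.324 ± 0.202 to 46.0 ± 11.14 CPM (7.12 ± 0.33, adjusted p = 6.3e-07). Its paralog ahrrb had 1 count in the 4 DMSO libraries and 331 in the 4 TCDD libraries, a ratio of 309.9 with an exact 95% counting interval of 55.25 to 12280. That interval lies above the list's median, so the median is the same with ahrrb at its lower bound. The poly(ADP-ribose) polymerase gene tiparp, which feeds back on AHR, rose from 41.6 ± 2.99 to 161 ± 37.9 CPM (1.95 ± 0.16, adjusted p = 9.9e-05). The forkhead gene foxq1b rose by 2.06 ± 0.25 on the log2 scale (adjusted p = 0.0013). The quinone reductase gene nqo1 rose least, from 82.0 ± 13.2 to 124 ± 11.8 CPM (0.59 ± 0.13, adjusted p = 0.020). Its call was lost without DMSO 3 (adjusted p = 0.0635), DMSO 4 (0.0528), TCDD 1 (0.0517) or TCDD 2 (0.0643). By camera the list ranked higher than other genes (adjusted p = 9.4e-26 over 37 lists), with adjusted p = 0.141 with an estimated correlation. That was the lowest value of the 37 lists, so with an estimated correlation none passed. The lack of a call in that version therefore does not set 1 list apart from another.

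**Figure D1:**
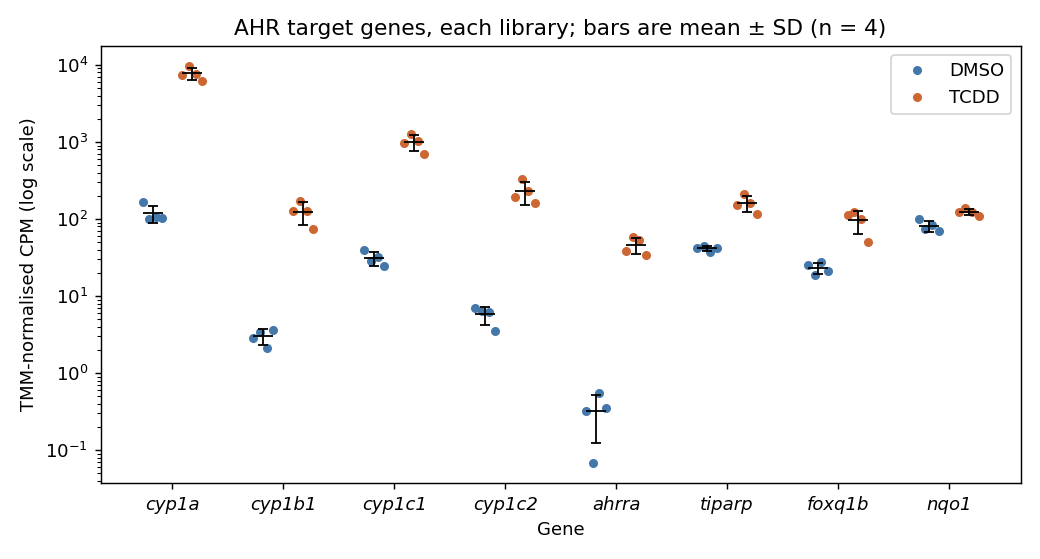
The vertical axis gives TMM-normalised CPM on a log scale for 8 AHR target genes, with 1 point per library, blue for DMSO and orange for TCDD, and black bars for the mean ± SD (n = 4). All 4 TCDD libraries sit above all 4 DMSO libraries for each gene, from nqo1 (82.0 to 124 CPM) to ahrra (0.324 to 46.0 CPM).

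The receptor gene ahr2 itself rose from 106 ± 14.1 to 215 ± 27.1 CPM (1.015 ± 0.13, adjusted p = 0.0016). In the list of AHR signalling components 2 of 10 members rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.536). The other calls were ahr1a (0.95 ± 0.22, adjusted p = 0.030) and the cochaperone gene ptges3a (-0.54 ± 0.11, adjusted p = 0.017). The call of ahr1a was lost without DMSO 3 (adjusted p = 0.0916), DMSO 4 (0.0716), TCDD 1 (0.0803) or TCDD 3 (0.0822). That of ptges3a was lost without DMSO 3 (0.0678), without TCDD 2 (0.0587), without both DMSO 1 and TCDD 2 (0.077) and with library size alone (0.0633).

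Outside the AHR list, the growth factor gene fgf7 had the largest rise among the named genes, from 4.37 ± 0.704 to 96.2 ± 26.7 CPM (4.46 ± 0.22, adjusted p = 8.8e-07). The glucuronosyltransferase genes ugt1b1 (2.855 ± 0.24, adjusted p = 0.00015) and ugt1b5 (2.04 ± 0.19, adjusted p = 0.00019) rose too, although reads of such paralogs can be counted at the wrong copy. The largest fall was that of the LIM domain gene fhl5, from 24.1 ± 9.13 to 2.47 ± 0.647 CPM (-3.28 ± 0.28, adjusted p = 0.00015). The keratin gene krt15 fell from 622 ± 200 to 118 ± 37.3 CPM (-2.40 ± 0.28, adjusted p = 0.0010), and the phosphate transporter gene slc34a2a from 31.6 ± 16.6 to 6.96 ± 2.26 CPM (adjusted p = 0.0087). The elastin gene elnb fell from 130 ± 18.6 to 41.2 ± 7.78 CPM (-1.66 ± 0.15, adjusted p = 0.00019). The secreted matrix gene spon2b (-1.56 ± 0.20, adjusted p = 0.0017) and cbln8 (-1.59 ± 0.31, adjusted p = 0.015) also fell. The chemokine gene ccl34b.1 fell by 1.74 ± 0.33 (adjusted p = 0.012), a call that was lost without both DMSO 1 and TCDD 2 (0.121).

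The calls of the remaining members of the 10 largest falls were lost in some fits that left out 1 library. Such fits have fewer samples, so a loss does not by itself show reliance on that library. The globin gene hbae5 fell by 2.11 ± 0.38 (adjusted p = 0.016), and its call was lost without TCDD 4 (0.0563). The intestinal genes alpi.2 (-1.80 ± 0.41, adjusted p = 0.040), a phosphatase, and enpp7.1 (-1.67 ± 0.35, adjusted p = 0.026), a sphingomyelinase, fell near the threshold. The call of alpi.2 was lost without DMSO 1 (0.106), DMSO 2 (0.0701), DMSO 3 (0.0829), TCDD 1 (0.0603), TCDD 2 (0.107), TCDD 3 (0.0519) or both DMSO 1 and TCDD 2 (0.241), with no filter (0.0685) and with offsets for length (0.0558). That of enpp7.1 was lost without DMSO 1 (0.063), DMSO 2 (0.0505), DMSO 3 (0.0545), TCDD 1 (0.0557), TCDD 2 (0.0582) or both (0.13).

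Across the 20522 genes tested, 1174 changed, 614 higher and 560 lower in TCDD, and 309 changed at least 2-fold (156 higher, 153 lower). Of the 1174, 1123 had no overlap between the groups (95.7%), against 13.95% of all genes tested and 2.857% given by chance. The 1174 were chosen by a test on the same values, so their share is no separate support for the calls. With library size alone the median log2 fold change of all genes shifted to 0.13, with 937 higher and 372 lower, so 71.6% of calls were higher against 52.3% with TMM factors. The count differed in fits that left out 1 library, which had fewer samples. It was 1854 without DMSO 2, 523 without DMSO 3, 652 without TCDD 1, 579 without TCDD 2 and 755 without TCDD 3. The calls lower in TCDD were 373 without TCDD 4. Without both DMSO 1 and TCDD 2 the count of changed genes was 616, of which 580 were among the 1174.

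Transcripts of organs other than the heart were abundant in every library. The summed CPM of the liver list was 48880 ± 10010 in DMSO and 47430 ± 3374 in TCDD, against 1923 ± 132.8 and 1718 ± 249 for the cardiomyocyte list. Skeletal muscle (19480 and 19190 CPM), skin (18950 and 16790 CPM), cartilage (12550 and 8784 CPM), intestine (11340 and 9776 CPM) and exocrine pancreas (10790 and 9516 CPM) also exceeded it. On library size alone the apolipoprotein gene apoa1b, chosen after its values were seen, was at 16620 to 24601 CPM, whereas the heart's myosin light chain gene myl7 was at 79.5 to 220 CPM. Among 14 lists of cell types, the summed CPM differed with an exact two-sided permutation p = 0.0286, the smallest possible with 4 against 4, for cartilage and for erythrocytes (7198 ± 1275 and 4681 ± 781.9 CPM), and with exact p = 0.8286 for liver and 0.229 for cardiomyocytes. After adjustment over the 14 lists both lowest values became 0.2. The groups below are therefore read as transcripts of the sampled material, not of heart cells alone.

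**Figure D2:**
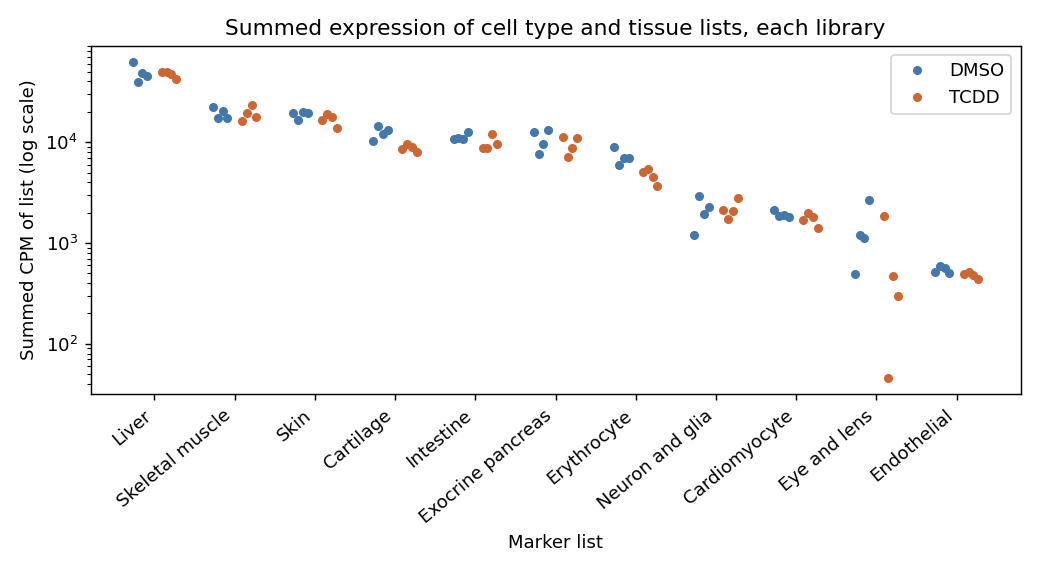
The vertical axis gives the summed CPM of each marker list, scaled to library size alone, on a log scale, with 1 point per library, blue for DMSO and orange for TCDD. The liver list lies at 39270 to 62810 CPM and the cardiomyocyte list at 1394 to 2116 CPM, while the eye and lens list runs from 45.7 to 2680 CPM.

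The change varied with transcript length. The shortest decile of genes by implied transcript length (up to 823.7 bases) had a median log2 fold change of -0.26 (-0.163 without DMSO 1, -0.12 with library size alone) and the longest 0.10 (0.0395 without DMSO 1, 0.152 without DMSO 2, 0.0532 without both DMSO 1 and TCDD 2, 0.217 with library size alone), and of the 139 calls in the shortest 119 were lower. Genes under 1000 bases of implied length held 29.0 ± 4.24% of the counts in DMSO and 24.1 ± 0.67% in TCDD (exact two-sided permutation p = 0.0857). The share was 34.03% in DMSO 1 and 23.7% in DMSO 2.

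**Figure D3:**
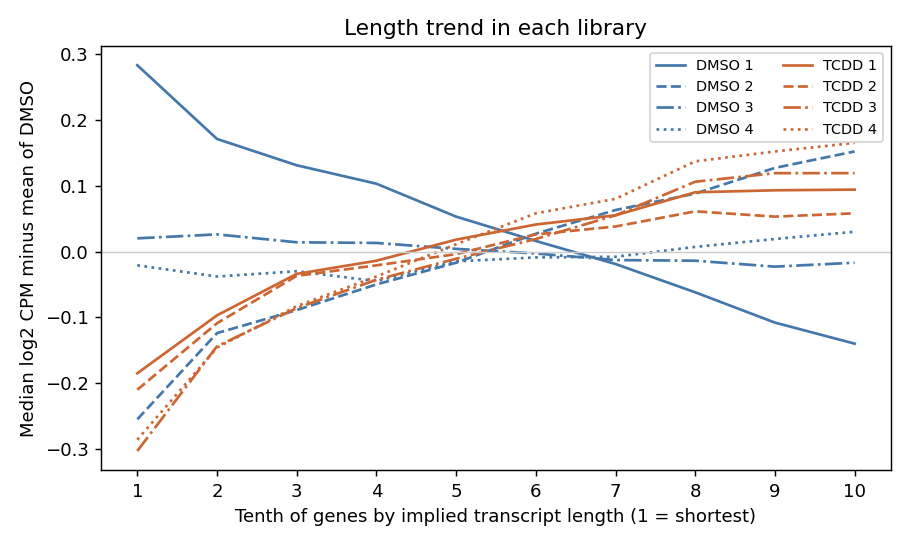
The horizontal axis gives deciles of genes by implied transcript length from the shortest, and the vertical axis the median log2 CPM minus the mean of the DMSO libraries, with 1 line per library, blue for DMSO and orange for TCDD. In the shortest decile DMSO 1 lies at 0.28, DMSO 2 at -0.255, the other DMSO libraries at -0.02 and 0.02, and the TCDD libraries at -0.30 to -0.185.

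Genes of lipid peroxidation and ferroptosis, the form of cell death driven by lipid peroxides, went both ways. Of 28 tested members 2 rose and 4 fell over all genes, and 6 rose and 6 fell adjusted over the list alone, with a median log2 fold change of -0.10 (0.035 with library size alone; camera adjusted p = 0.536). Camera looks for change in 1 direction. Fry's mixed test asks whether members changed in either direction, without comparison to other genes, and gave adjusted p = 0.00022. It also passed for AHR signalling components (4.4e-05), calcium handling (0.00020), cardiac transcription factors (7.9e-06), retinoid metabolism (7.8e-06), p53 (2.0e-05) and inflammation (1.2e-05). Among the lists it did not pass were cell cycle (0.473), circadian clock (0.578) and cardiac stress (0.126). The lipid peroxide reductase gene gpx4a fell from 723 ± 216 to 345 ± 49.0 CPM (-1.07 ± 0.22, adjusted p = 0.017). Its implied length was 650 bases, in the range where genes were lower in general, and with offsets for length its change was -0.84 (adjusted p = 0.021). The ferritin gene fth1b (-0.71 ± 0.14, adjusted p = 0.013) and the glutathione-degrading gene chac1 (-0.85 ± 0.18, adjusted p = 0.017) also fell. The ferroptosis suppressor gene aifm2 rose from 45.9 ± 3.30 to 69.1 ± 5.86 CPM (0.59 ± 0.10, adjusted p = 0.0070), and the haem oxygenase gene hmox1a rose from 18.6 ± 2.63 to 38.7 ± 15 CPM (1.06 ± 0.22, adjusted p = 0.019). The paralog gpx4b (-0.26 ± 0.12, adjusted p = 0.237), acsl4a (0.43 ± 0.13, adjusted p = 0.0848; 0.0359 with DESeq2) and ptgs2a (-0.38 ± 0.15, adjusted p = 0.163; 0.043 without TCDD 4) did not pass, and slc7a11 had too few counts to test.

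The calls of the lipid peroxidation list, except that of aifm2, were each lost in fits that left out 1 library. Such fits have fewer samples, so a loss does not by itself show reliance on that library. Without DMSO 3 aifm2 alone was called, without TCDD 2 the count was 3, without TCDD 1 it was 4, and without both DMSO 1 and TCDD 2 it was 1. The call of gpx4a was lost without DMSO 3 (adjusted p = 0.0609), TCDD 2 (0.0517) or both DMSO 1 and TCDD 2 (0.109). That of fth1b was lost without DMSO 3 (0.052) or both (0.0508). That of chac1 was lost without DMSO 3 (0.0669), TCDD 1 (0.0514), TCDD 2 (0.0547) or both (0.053). That of hmox1a was lost without DMSO 3 (0.0673), DMSO 4 (0.0508) or both (0.0754).

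In the antioxidant and glutathione list 5 of 30 members rose and 1 fell, and 8 rose and 3 fell adjusted over the list alone. Among the rises were nqo1, also in the AHR target list, and hmox1a, also in the lipid peroxidation list. The stress-response transcription factor gene nfe2l2b rose from 15.6 ± 1.53 to 50.6 ± 9.66 CPM (1.695 ± 0.15, adjusted p = 0.00015). The glutathione peroxidase gene gpx1b fell from 25.4 ± 10.6 to 11.3 ± 1.11 CPM (-1.17 ± 0.24, adjusted p = 0.016). The list ranked higher by camera with a median log2 fold change of 0.16 (adjusted p = 0.046), with adjusted p = 0.855 with an estimated correlation. That call was lost without DMSO 2 (0.653, 5 higher and 7 lower), DMSO 4 (0.0806, 2 higher), TCDD 2 (0.0569, 2 higher) or TCDD 3 (0.0625, 3 higher). The calls numbered 1 higher without DMSO 3, 8 without DMSO 1, 3 without TCDD 1 and 2 without both DMSO 1 and TCDD 2. With the genes of other tissues left out the camera adjusted p was 0.052.

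**Figure D4:**
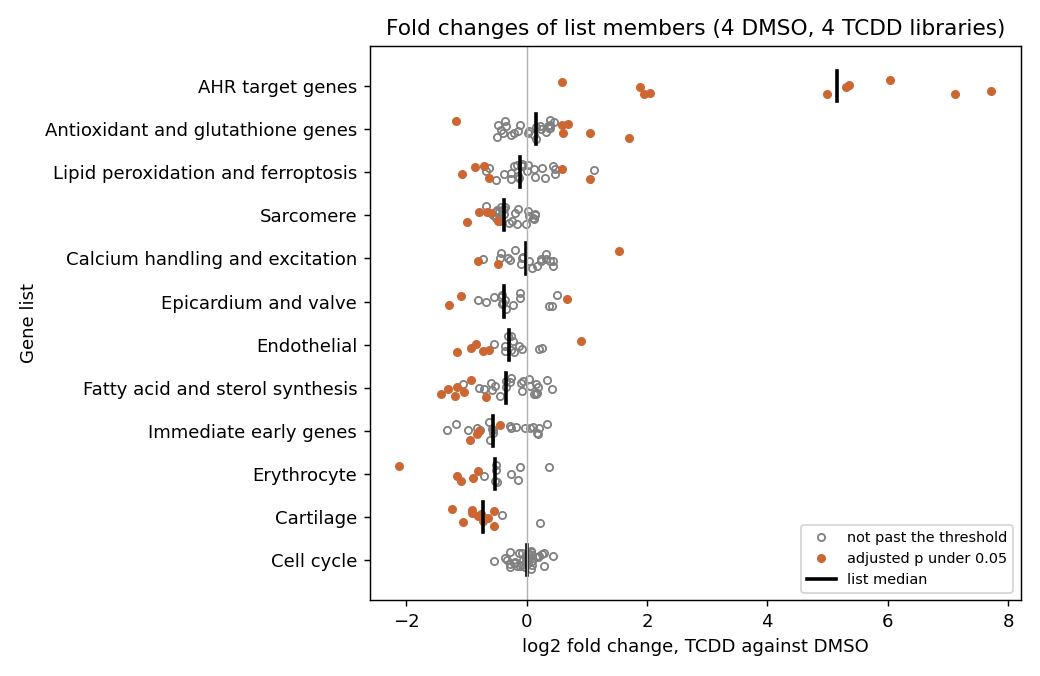
The horizontal axis gives the fitted log2 fold change of each tested member of 12 gene lists, TCDD against DMSO; filled points passed the test, open points did not, and black lines are list medians. AHR targets lie to the right (median 5.15), cartilage genes to the left (median -0.73) and cell cycle genes about 0, and the point farthest right is ahrrb, whose fitted value rests on 1 DMSO count.

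Sarcomere transcripts need not come from heart muscle alone here, since the skeletal muscle list (19480 CPM in DMSO) exceeded the cardiomyocyte list (1923 CPM). Of the 29 members of the sarcomere list 5 fell, 0 rose and 24 did not pass. Adjusted over the list alone 11 fell, and the median log2 fold change was -0.38 (camera adjusted p = 1.2e-05). With an estimated correlation, with which no list passed, the adjusted p was 0.731. The calls included the cardiac actin gene actc1c (172 ± 24.5 to 114 ± 10.7 CPM; -0.59 ± 0.125, adjusted p = 0.019), the myosin light chain gene myl7 (-0.99 ± 0.22, adjusted p = 0.023) and the ventricular myosin heavy chain gene vmhc, listed as myh7 (-0.48 ± 0.12, adjusted p = 0.034). The atrial myosin heavy chain gene myh6 did not pass (-0.24 ± 0.16, adjusted p = 0.406). The call of actc1c was lost without DMSO 3 (0.0688) or TCDD 1 (0.0673). That of myl7 was lost without DMSO 1 (0.0589), DMSO 3 (0.0673), TCDD 3 (0.0687) or both DMSO 1 and TCDD 2 (0.052). That of myh7 was lost without DMSO 3 (0.104), TCDD 1 (0.0941), TCDD 3 (0.0772) or TCDD 4 (0.0673), and with library size alone (0.0901). Without DMSO 3 no sarcomere gene was called, and 3 were called without DMSO 1, 1 without TCDD 1 or TCDD 3 and 2 without TCDD 4. In the cardiomyocyte list, 8 of whose 11 members the sarcomere list also held, myl7 and myh7 fell and 0 rose, 5 fell adjusted over the list alone, and the median was -0.38 (camera adjusted p = 0.0034; adjusted p = 0.7995 with an estimated correlation).

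Natriuretic peptide genes, markers of cardiac strain, did not differ detectably. The values were 101 ± 29.3 and 99.1 ± 39.5 CPM for nppa (-0.03 ± 0.28, adjusted p = 0.966) and 10.55 ± 6.95 and 11.7 ± 5.63 CPM for nppb (0.16 ± 0.45, adjusted p = 0.874), and neither sign was stable. The value of nppa was positive without DMSO 1 (0.184), TCDD 3 (0.022) or TCDD 4 (0.167), with library size alone (0.12) and with offsets for length (0.034), and that of nppb was negative without DMSO 2 (-0.016), DMSO 4 (-0.013) or TCDD 2 (-0.215). Of 15 members of the cardiac stress list, fhl1a fell (-1.13 ± 0.25, adjusted p = 0.024) and 1 rose, with the same counts adjusted over the list alone (median -0.075, 0.063 with library size alone; camera adjusted p = 0.396). The call of fhl1a was lost without DMSO 3 (0.0673), TCDD 2 (0.0559) or both DMSO 1 and TCDD 2 (0.0782), and no member was called without both. The rise, that of xirp1, was not called without DMSO 2, DMSO 3, TCDD 1, TCDD 2 or TCDD 3, or with offsets for length (adjusted p = 0.14).

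Among 22 genes of calcium handling and excitation 1 rose and 2 fell, also adjusted over the list alone (median -0.01, 0.12 with library size alone; camera adjusted p = 0.912). The inward rectifier potassium channel gene kcnj2a rose from 14.65 ± 0.464 to 42.65 ± 11.3 CPM (1.54 ± 0.18, adjusted p = 0.00098). The phospholamban gene pln fell from 25.5 ± 2.198 to 14.6 ± 2.78 CPM (-0.81 ± 0.14, adjusted p = 0.0084). Only 1 fall was called without DMSO 3, TCDD 1, TCDD 2, TCDD 4 or both DMSO 1 and TCDD 2. Of 21 cardiac transcription factor genes 2 rose and 1 fell, also adjusted over the list alone (median -0.03, 0.10 with library size alone; camera adjusted p = 0.906). The ventricular gene hey2 fell from 7.30 ± 0.653 to 4.24 ± 0.453 CPM (-0.78 ± 0.145, adjusted p = 0.011), and its call was lost without both DMSO 1 and TCDD 2 (0.0535), when no member was called. The rises numbered 0 without DMSO 3 or TCDD 2 and 1 without TCDD 1, TCDD 3 or TCDD 4.

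In the epicardium and valve list 1 of 18 members rose and 2 fell, and 4 rose and 8 fell adjusted over the list alone (median -0.375, camera adjusted p = 0.0125). With an estimated correlation the list had adjusted p = 0.714. The chondrogenic and valve factor gene sox9b fell from 28.45 ± 3.23 to 11.6 ± 1.89 CPM (-1.29 ± 0.14, adjusted p = 0.00062). The epicardial gene tbx18 rose from 6.955 ± 0.666 to 11.09 ± 1.69 CPM (0.67 ± 0.145, adjusted p = 0.021), and its call was lost without TCDD 2 (0.0732), TCDD 3 (0.0727) or both DMSO 1 and TCDD 2 (0.0921). The falls numbered 1 without DMSO 1, DMSO 3, TCDD 1, TCDD 3, TCDD 4 or both, and the rises 2 without DMSO 2.

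Cartilage genes fell together. Of 14 tested members 12 fell and 0 rose, 13 fell adjusted over the list alone, and the median log2 fold change was -0.73 (camera adjusted p = 6.2e-14). The list had adjusted p = 0.352 with an estimated correlation, and fry's directional test gave adjusted p = 0.0011. Besides it only the AHR target list passed fry's directional test (adjusted p = 4.6e-05), and the next lowest was the pigment cell list (0.0645). The Gla protein gene ucmab fell from 97.2 ± 12.3 to 41.0 ± 2.12 CPM (-1.245 ± 0.11, adjusted p = 0.00015), and the proteoglycan link gene hapln1a from 115 ± 11.2 to 55.6 ± 5.88 CPM (-1.05 ± 0.11, adjusted p = 0.00056). The matrix gene epyc fell from 405 ± 25.0 to 216 ± 21.2 CPM (-0.91 ± 0.12, adjusted p = 0.0016) and the chondromodulin gene cnmd from 375 ± 42.1 to 199 ± 18.7 CPM (-0.91 ± 0.125, adjusted p = 0.0022). The fits that left out 1 library called 9 to 12 of the 14.

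Of 18 endothelial genes 5 fell, 1 rose and 12 did not pass, 7 fell and 1 rose adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.00018; adjusted p = 0.714 with an estimated correlation). The fenestral diaphragm gene plvapb fell from 91.2 ± 9.998 to 47.9 ± 3.04 CPM (-0.93 ± 0.11, adjusted p = 0.00081). The transcription factor gene sox18 (-0.83 ± 0.12, adjusted p = 0.0030) and the receptor gene tek (-1.16 ± 0.18, adjusted p = 0.0037) fell, and the von Willebrand factor gene vwf rose (0.90 ± 0.14, adjusted p = 0.0046). The summed CPM of the list was 541.2 ± 39.81 in DMSO and 481.7 ± 28.48 in TCDD (exact permutation p = 0.0571). With TMM-scaled library sizes, chosen after the data were seen, it was 567 ± 47.45 and 460 ± 39.7 with no overlap between the groups (exact p = 0.0286, 0.133 adjusted over the 14 lists).

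In the erythrocyte list 5 of 14 members fell and 0 rose, 9 fell adjusted over the list alone, and the median was -0.52 (camera adjusted p = 8.7e-06; adjusted p = 0.714 with an estimated correlation). The erythroid gene hemgn fell from 39.4 ± 6.20 to 22.4 ± 2.77 CPM (-0.81 ± 0.13, adjusted p = 0.0056). The embryonic globin genes hbae1.3 (-1.09 ± 0.22, adjusted p = 0.016) and hbbe2 (-1.15 ± 0.25, adjusted p = 0.020) fell, with calls lost without DMSO 3 (0.0512 for hbae1.3) and TCDD 3 (0.061 for hbbe2). Globin transcripts are short and alike, and hbbe2 changed by -0.74 with offsets for length. The fits without DMSO 3, TCDD 3 or TCDD 4 called 3 members.

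Of 30 genes of fatty acid and sterol synthesis 7 fell, 0 rose and 23 did not pass, 11 fell and 1 rose adjusted over the list alone, with a median of -0.34 (camera adjusted p = 0.00086; adjusted p = 0.714 with an estimated correlation). The lanosterol synthase gene lss fell from 19.9 ± 9.11 to 7.99 ± 0.801 CPM (-1.31 ± 0.27, adjusted p = 0.018), and hmgcra, which encodes the rate-limiting enzyme of sterol synthesis, from 96.1 ± 30.2 to 42.2 ± 11.8 CPM (-1.185 ± 0.25, adjusted p = 0.019). The call of lss was lost without TCDD 2 (0.0538) and that of hmgcra without DMSO 3 (0.0512), TCDD 2 (0.0525) or both DMSO 1 and TCDD 2 (0.117). The members called lower numbered 3 without DMSO 1, 14 without DMSO 2, 1 without DMSO 3, 4 without DMSO 4, 3 without TCDD 1, 0 without TCDD 2, 4 without TCDD 4 and 1 without both.

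Of 37 genes of oxidative phosphorylation 35 had a negative log2 fold change, with a median of -0.25, but 1 passed the test, also adjusted over the list alone. That gene was cox6a2 (-0.95 ± 0.18, adjusted p = 0.010), with an implied length of 263 bases and a change of -0.55 with offsets for length (adjusted p = 0.0114). The list ranked lower by camera (adjusted p = 0.00013; adjusted p = 0.812 with an estimated correlation), and with offsets for length that call was lost (median -0.05, adjusted p = 0.128). Without DMSO 2 the calls were 13. Of 29 genes of fatty acid oxidation and uptake the fatty acid transporter gene cd36 fell from 341 ± 59 to 217 ± 22.1 CPM (-0.65 ± 0.14, adjusted p = 0.020) and 0 rose, also adjusted over the list alone (median -0.04, 0.080 with library size alone; camera adjusted p = 0.294, 0.0455 without DMSO 2 with 3 calls). The call of cd36 was lost without DMSO 3 (0.0524), TCDD 1 (0.0589), TCDD 2 (0.0556) or both DMSO 1 and TCDD 2 (0.0506). Of 33 genes of glycolysis and hypoxia 1 rose and 1 fell, and 1 rose and 2 fell adjusted over the list alone (median 0.03, camera adjusted p = 0.964). The glycolytic gene gpib fell from 39.6 ± 2.98 to 26.6 ± 2.58 CPM (-0.58 ± 0.11, adjusted p = 0.011). The rise, that of hk2, was not called without DMSO 3, DMSO 4, TCDD 1, TCDD 2, TCDD 4 or both DMSO 1 and TCDD 2, or with offsets for length (adjusted p = 0.05025), and the falls numbered 4 without DMSO 2 and 2 without TCDD 1, with library size alone or with offsets for length.

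Of 24 immediate early genes, induced by acute stimuli, 4 fell, 0 rose and 20 did not pass, 14 fell adjusted over the list alone, and the median was -0.56 (camera adjusted p = 0.00011; adjusted p = 0.714 with an estimated correlation). The phosphatase gene dusp1 fell from 195.5 ± 31.3 to 111 ± 18.2 CPM (-0.82 ± 0.15, adjusted p = 0.0095). The antiproliferative gene btg2 fell too (-0.93 ± 0.20, adjusted p = 0.020), with its call lost without TCDD 2 (0.0671), TCDD 3 (0.0639) or both DMSO 1 and TCDD 2 (0.111). The list had 8 calls without DMSO 2, 2 without DMSO 4 and 1 without TCDD 2, without TCDD 3 or without both DMSO 1 and TCDD 2. In the extracellular matrix list 2 of 38 rose and 3 fell, and 3 rose and 12 fell adjusted over the list alone (median -0.19, camera adjusted p = 0.00086; adjusted p = 0.740 with an estimated correlation). The intermediate filament gene vim fell from 136 ± 16.8 to 89.5 ± 3.12 CPM (-0.61 ± 0.11, adjusted p = 0.0092), beside elnb. The matricellular protein gene ccn2b rose (0.62 ± 0.13, adjusted p = 0.016), with its call lost without DMSO 3 (0.0597) or TCDD 1 (0.0512). The list's rises numbered 0 without DMSO 3 or TCDD 1 and 1 without DMSO 1, DMSO 2, TCDD 2 or both DMSO 1 and TCDD 2, and its falls 6 without DMSO 2.

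Of 25 inflammation genes 4 rose and 1 fell, and 6 rose and 5 fell adjusted over the list alone (median 0.05, camera adjusted p = 0.835). The cytokine gene il11a rose from 1.107 ± 0.0906 to 2.68 ± 0.763 CPM (1.27 ± 0.25, adjusted p = 0.013) and the interferon signalling gene stat1b from 5.26 ± 1.94 to 11.5 ± 1.60 CPM (1.12 ± 0.23, adjusted p = 0.016). The call of il11a was lost without DMSO 3 (0.0515), and that of stat1b without DMSO 3 (0.0578) or both DMSO 1 and TCDD 2 (0.0794). No inflammation gene was called higher without DMSO 3, and 2 were without TCDD 2 or without both. The fall, that of the chemokine gene cxcl18b, was not called without TCDD 1, TCDD 2 or both, or with offsets for length (-0.59 from -0.92, adjusted p = 0.149), and the falls numbered 2 without DMSO 2 and 3 without TCDD 4.

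Of 24 p53 and apoptosis genes 2 rose and 2 fell, and 4 rose and 4 fell adjusted over the list alone (median 0.01, camera adjusted p = 0.964). The executioner caspase gene casp3b rose from 8.635 ± 1.29 to 16.1 ± 1.63 CPM (0.90 ± 0.14, adjusted p = 0.0042). The stress gene gadd45ba fell from 112 ± 31.8 to 57.95 ± 8.62 CPM (-0.95 ± 0.19, adjusted p = 0.015), with its call lost without both DMSO 1 and TCDD 2 (0.0723). The list had 1 rise without DMSO 1, DMSO 2, DMSO 4, TCDD 1, TCDD 2, TCDD 3 or both, 4 falls without DMSO 2, and 1 fall without DMSO 3, DMSO 4, TCDD 1, TCDD 2 or both. No gene passed in the cell cycle list of 36 (camera adjusted p = 0.844), the circadian clock list of 23 (0.964) or the heat shock list of 16 (0.131) in edgeR with treatment as the only term, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 these lists held 4, 1 and 5 genes. DESeq2 called 0, 0 and 2 and limma-voom 0 in each, while 1 cell cycle gene was called without DMSO 2 and 1 heat shock gene without DMSO 1, without DMSO 4 or without both DMSO 1 and TCDD 2. Of 22 genes of endoplasmic reticulum and amino acid stress chac1 fell and 0 rose, also adjusted over the list alone (median -0.17, camera adjusted p = 0.131; 0.0347 without DMSO 4, with 3 falls, and 0.0177 without TCDD 4; 2 falls without DMSO 2). Its call was lost without DMSO 3 (0.0669), TCDD 1 (0.0514), TCDD 2 (0.0547) or both DMSO 1 and TCDD 2 (0.053).

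Of 24 genes of phase II conjugation and export 2 rose and 3 fell, and 2 rose and 5 fell adjusted over the list alone (median -0.15, camera adjusted p = 0.396). The sulfotransferase gene sult6b1 rose from 229 ± 48.5 to 571 ± 72.4 CPM (1.32 ± 0.16, adjusted p = 0.0012). The sulfotransferase gene sult1st3 fell from 86.3 ± 23.7 to 42.3 ± 9.88 CPM (-1.03 ± 0.21, adjusted p = 0.017), with its call lost without DMSO 3 (0.0535) or both DMSO 1 and TCDD 2 (0.0717). No member was called lower without DMSO 3 or without both, and 1 was without TCDD 1 or TCDD 2. The rises numbered 1 without DMSO 2, DMSO 3, TCDD 1, TCDD 2, TCDD 3 or TCDD 4. Of 19 genes of retinoid metabolism 1 rose and 1 fell, also adjusted over the list alone (median -0.09, 0.031 with library size alone; camera adjusted p = 0.743). The retinol dehydrogenase gene rdh10a rose from 39.9 ± 2.40 to 58.5 ± 4.47 CPM (0.55 ± 0.098, adjusted p = 0.0085). The falls of that list numbered 2 without DMSO 1, 3 without DMSO 2 and 0 without TCDD 1, TCDD 2 or TCDD 4.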

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

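The tests of the length trend without DMSO 1, and of cartilage genes with length offsets and without DMSO 1 and TCDD 2, were set before their results were seen; the other tests, the splits of the samples included, were chosen only after the result was seen.

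A library lay farther from the other 3 of its group than Dixon's 95% limit allows in 19 of 416 groups checked, and chance gives about 20.8. In DMSO 1, cyp1a stood at 164 CPM (others 101 to 106), mcm7 at 87.6 (67.85 to 69.8), serpinh1b at 66.4 (14.3 to 16.7), cd74a at 3.91 (1.82 to 2.03) and lta4h at 257 (176 to 187). In DMSO 2, gins2 stood at 4.85 CPM (10.06 or more), the summed fatty acid and sterol synthesis list at 1592 (1833 to 1860.0) and the summed skin list at 16726 (19450 to 20070). In DMSO 3, ahrrb stood at 0.0699 CPM, which was 1 count against 0 in the others. In DMSO 4, nfatc1 stood at 6.91 CPM (11.95 to 12.8), hk2 at 19.6 (26.95 to 27.1), sox18 at 23.5 (20.7 to 21.01), opn1sw2 at 105 (32.7 to 39.8) and the summed AHR target list at 317 (350.4 to 354). In TCDD 2, lta4h stood at 158 CPM (135 to 136) and dct at 2.15 (3.935 to 4.37). In TCDD 3, acsl4a stood at 182 CPM (132 to 135). In TCDD 4, enpp7.1 stood at 8.56 CPM (18.5 to 20.3) and cxcl18b at 2.06 (1.59 to 1.62). These distances depended on the scaling, which was TMM-scaled library sizes for genes and library size alone for the sums of lists: on the other scale 6 of the 16 values of genes and 0 of the 3 sums stayed past the limit.

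For the counts of genes the real split stood apart from the others. Of 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many changed genes (1174), genes higher (614), genes lower (560) or genes changed at least 2-fold (309), and the highest other split gave 34 for each, counted in either direction. That is the smallest share 35 splits can give. Every other split mixed DMSO and TCDD libraries, so differences between the treatments widened the spread within its sides. The splits alone therefore do not exclude chance. Chance cannot be excluded for the number of lists passing camera: 9 of 35 splits gave at least the real 16, and the highest other gave 21.

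Transcripts of other organs were abundant in libraries whose tissue is given as heart. In all 8 libraries 6 of 6 lists (liver, exocrine pancreas, intestine, skeletal muscle, skin and cartilage) had a higher summed CPM than the cardiomyocyte list. Tissue or RNA of other organs in the samples would give this. The comparison restates the abundance that prompted it, and the lists differ in size (liver 25 members, cardiomyocyte 11), so it is no separate test. Reads of heart genes counted at paralogs are argued against as the source for the liver list only, which exceeded the cardiomyocyte list at least 21.2 times in every library. For the other lists, skeletal muscle among them, that ratio is no test of miscounting. On library size alone the apolipoprotein gene apoa1b stood at 16620 to 24601 CPM and the liver fatty acid-binding gene fabp10a at 1469 to 4353 CPM, both chosen after their values were seen. Which organs were sampled, and whether a change in a list is one in heart cells, stays open.

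Short genes were lower in TCDD, with a median log2 fold change of -0.26 in the shortest decile, a size that depended on the scaling (-0.12 with library size alone). DMSO 1 alone is argued against as the source, since the median stayed at -0.163 without it. The trend is also argued against as the whole source of the calls, because 999 of 1174 called genes were called again with length offsets. Length-dependent differences between single libraries stay open, since the decile's median ranged over 0.538 among the 4 DMSO libraries, more than between the groups. A TCDD effect on short transcripts may add to them and was not tested.

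Cartilage genes were lower in TCDD. The length trend and the libraries DMSO 1 and TCDD 2 are each argued against as the source, since 12 of 14 members were called lower with length offsets and 12 of 14 without both libraries. The same fold loss of every member, as from less cartilage with no other source of these transcripts, was set against the spread of the members. The SD of their changes was 2.54 times the median SE of a member. Much of that SD rests on matn4, the 1 member with a positive change (log2 fold change 0.22, adjusted p = 0.403, list mean -0.695). The spread therefore does not decide about a same fold loss. The exceptions matn4 and sox9a (-0.40, adjusted p = 0.106) were named after their values were seen. Less cartilage in samples where other tissues express some members, and an effect of TCDD on cartilage genes, may each account for the pattern and stay open.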

How the results depend on the processing

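The length offsets, the removal of DMSO 1 and TCDD 2 together, and TMM-scaled library sizes for the summed CPM of lists were chosen only after the data were seen. The value of cyp1a (log2 fold change 5.91 to 6.235 with 1 library left out) and the calls of at least 9 of 10 AHR target genes held in every fit that left out 1 library. The number of changed genes, 1174, was 2007 with DESeq2, 616 without DMSO 1 and TCDD 2, 327 at an adjusted p under 0.01, 2070 at 0.1, and 523 to 1854 with 1 library left out. Genes higher, 614, were 939 with DESeq2, 937 with library size alone, 338 without DMSO 1 and TCDD 2, and 294 to 682 with 1 library left out. Genes lower, 560, were 1068 with DESeq2, 372 with library size alone, 278 without both, and 229 to 1172 with 1 library left out. Genes changed at least 2-fold, 309, were 157 with a mean of at least 10 CPM, where 11083 genes were tested, and 194 without both. The other alternatives kept these counts within 1.5 times, the replicate block (1347 changed) and limma-voom (1056) among them, and DESeq2 shared 1162 of the 1174 calls. On simulated data, with fewer changed genes and no length trend, DESeq2 made more false calls (20.1% against 7.73%). Those data were drawn with edgeR's dispersions, which may favour edgeR, so the shares do not rank the tools on the real data. The AHR target list had a camera adjusted p = 0.141 with an estimated correlation. Lipid peroxidation calls, 6, were 1 without DMSO 1 and TCDD 2 and 1 to 8 with 1 library left out. The sign reversed for nppa (log2 fold change 0.12 with library size alone, 0.034 with length offsets, -0.315 to 0.184 with 1 library left out) and for nppb (-0.215 to 0.719), neither of which passed the test. With TMM-scaled library sizes the ratio of summed CPM, TCDD over DMSO, reversed for macrophage genes (0.928 from 1.034, exact p = 0.771), neutrophil genes (0.922 from 1.027, exact p = 0.543) and neuron and glia genes (0.976 from 1.052, exact p = 0.886), endothelial genes moved from exact p = 0.0571 to 0.0286, and the other 10 lists kept their direction and their side of 0.05. Apart from the fewer samples or genes of some fits and the thresholds, the cause was not tested.

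Of 103 named genes that were called, DESeq2 kept 103, limma-voom 99, the length offsets 95, library size alone 91, the block 96, and the removal of both libraries 61; leaving out 1 library kept 59 (without DMSO 3) to 97 (without DMSO 2), and no called gene reversed. Over the tested genes the deviations from group means of same-numbered samples correlated at -0.29, -0.22, 0.09 and 0.28, and the highest correlation (0.52) was between DMSO 1 and TCDD 2. The replicate block called 0 cell cycle genes, 2 circadian clock genes, 3 heat shock genes (camera adjusted p = 0.0218) and 14 immediate early genes. The named genes it did not call were hbae5 (adjusted p = 0.0863), xirp1 (0.0666), hk2 (0.054), pnp4a (0.0553), cyt1l (0.1556), gadd45aa (0.0579) and has2 (0.0658). With library size alone the calls were 10 higher in the antioxidant list, 3 higher and 1 lower in the epicardium and valve list and in the skin list, 4 higher and 1 lower in the p53 list, 4 higher in the liver list, 1 lower in the calcium handling list and in the cardiomyocyte list and 0 in the exocrine pancreas list, and the neutrophil and skeletal muscle lists passed camera (adjusted p = 0.0379 for each). With length offsets they were 4 lower in the epicardium and valve list, 1 higher and 5 lower in the extracellular matrix list, 3 higher and 1 lower in the p53 list and in the skin list, 2 lower in the neutrophil list and 2 higher in the liver list. The set length and GC correction was not run as such, and the alternatives for normalized values did not apply. At this depth a gene at 3 counts stands at 0.198 to 0.214 CPM. In the simulated data, with their fewer changed genes and no length trend, 16.6% of 1.5-fold changes were called.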

Other observations

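The test in the last paragraph of this part was chosen only after the result was seen.

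Genes of other organs were tested in the same way. Of 23 liver genes the copper-carrying protein gene cp rose from 328 ± 71.8 to 641 ± 176 CPM (log2 fold change 0.97 ± 0.21, adjusted p = 0.020) and 0 fell, while 2 rose and 2 fell adjusted over the list alone (median -0.11, 0.034 with library size alone; camera adjusted p = 0.755). The call of cp was lost without DMSO 3 (0.0829), DMSO 4 (0.0571), TCDD 1 (0.0519) or TCDD 2 (0.0515), and liver genes called numbered 2 without DMSO 1 and 5 without DMSO 2. In the intestine list 3 of 14 fell and 0 rose, 4 fell adjusted over the list alone, and the median was -0.35 (camera adjusted p = 0.00059; adjusted p = 0.714 with an estimated correlation). The fatty acid-binding gene fabp2 fell from 1368 ± 272 to 793 ± 98.5 CPM (-0.79 ± 0.17, adjusted p = 0.022). Its call was lost without DMSO 3 (0.0597), DMSO 4 (0.0588), TCDD 1 (0.0711), TCDD 2 (0.0752) or both DMSO 1 and TCDD 2 (0.0746), and with offsets for length (log2 fold change -0.45, adjusted p = 0.073). Without TCDD 1 no intestine gene was called, and 1 was without TCDD 2. In the exocrine pancreas list 1 of 19 fell and 0 rose, also adjusted over the list alone, and all 19 had a negative change (median -0.40, camera adjusted p = 0.0014; adjusted p = 0.812 with an estimated correlation). With offsets for length the median was -0.26, the camera adjusted p was 0.0356 and no member was called. The camera call was lost without both DMSO 1 and TCDD 2 (0.423), the members called were 5 without DMSO 2, and none was called without DMSO 3, DMSO 4, TCDD 1, TCDD 2, TCDD 3 or both. Of 25 skeletal muscle genes edgeR and limma-voom called 0 and DESeq2 1, also 0 adjusted over the list alone, with 7 at an unadjusted p under 0.05 (median -0.27, camera adjusted p = 0.115). By camera that list passed without DMSO 2 (0.0107, with 3 calls), DMSO 4 (0.0316) or TCDD 3 (0.00881).

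In the skin list 2 of 20 rose and 2 fell, and 4 rose and 3 fell adjusted over the list alone (median -0.15, camera adjusted p = 0.964). The secreted protein gene agr1 rose from 57.5 ± 9.36 to 138 ± 27.6 CPM (1.26 ± 0.16, adjusted p = 0.0013) and the annexin gene anxa1b from 153 ± 31.9 to 272 ± 27.5 CPM (0.83 ± 0.15, adjusted p = 0.010). The keratin gene krtt1c19e fell from 1131 ± 307 to 402 ± 121 CPM (-1.49 ± 0.26, adjusted p = 0.0078), with its call lost without both DMSO 1 and TCDD 2 (0.06). The falls numbered 1 without DMSO 1, DMSO 3, DMSO 4, TCDD 1, TCDD 3 or TCDD 4 and 0 without both. Of 18 neuron and glia genes the myelin gene mbpa fell from 112 ± 7.74 to 78.25 ± 3.99 CPM (-0.51 ± 0.096, adjusted p = 0.011; 0.0831 with library size alone) and 0 rose, also adjusted over the list alone (median 0.085, -0.02 without both DMSO 1 and TCDD 2; camera adjusted p = 0.964). The falls numbered 2 without DMSO 1, and 1 member rose without TCDD 4.

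Of 12 pigment cell genes 3 fell and 0 rose, also adjusted over the list alone (median -0.36, camera adjusted p = 0.0018; adjusted p = 0.714 with an estimated correlation). The melanin synthesis gene tyrp1a fell from 7.11 ± 0.706 to 3.67 ± 0.995 CPM (-0.95 ± 0.20, adjusted p = 0.018), with its call lost without DMSO 3 (0.0679), when no member was called, and 1 was called without DMSO 1, TCDD 1, TCDD 2, TCDD 4 or both DMSO 1 and TCDD 2, with library size alone and with limma-voom. Of 9 neutrophil genes the lysozyme gene lyz fell from 17.0 ± 3.89 to 8.14 ± 0.641 CPM (-1.06 ± 0.16, adjusted p = 0.0038), and 1 rose and 4 fell adjusted over the list alone (median -0.37, camera adjusted p = 0.115). By camera the neutrophil list passed without DMSO 4 (0.0372) or TCDD 4 (0.039), with 2 falls in each, and had 3 falls without DMSO 2. Of 12 macrophage genes 2 fell and 0 rose, and 1 rose and 4 fell adjusted over the list alone (median -0.065, 0.079 with library size alone; camera adjusted p = 0.345). The granulin gene grn1 was at 9.87 ± 4.79 and 3.82 ± 0.548 CPM (-1.36 ± 0.29, adjusted p = 0.021), with its call lost without DMSO 3 (0.0578), TCDD 1 (0.0582) or TCDD 2 (0.0559). No macrophage gene was called without DMSO 3 or TCDD 2, 4 were called without DMSO 2, and 1 was without DMSO 1, DMSO 4, TCDD 1 or both DMSO 1 and TCDD 2.

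Eye and lens genes differed widely between libraries of the same group. Their summed CPM ran from 45.7 (TCDD 2) to 2680 (DMSO 4), at 1374 ± 926.7 in DMSO and 667.8 ± 809.3 in TCDD (exact permutation p = 0.314). All 18 members had a negative change (median -0.805), edgeR called 0 of them, also adjusted over the list alone, with 3 at an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 2. The list passed camera (adjusted p = 0.00018) but had adjusted p = 0.7995 with an estimated correlation. That correlation between members within groups was 0.881. A list that marks no tissue, oxidative phosphorylation, also had a high value (0.786). The correlation therefore does not by itself point to eye tissue in differing amounts between samples, which stays open.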
